A study of Mus musculus with 6 samples.

How the data were processed

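MA-10 is a cell line from a mouse Leydig cell tumour, the cell type that makes steroid hormones in the testis. Total RNA was taken 48 h after the cells received either a small interfering RNA against the transcription factors MEF2A and MEF2D (siRNA MEF2, 3 samples) or a scrambled one (siRNA control, 3 samples). Each sample was hybridised to 1 biotin-labelled, 1-colour Affymetrix whole-transcript array. The labels number the samples of each group from 1 to 3 and do not say whether they came from separate cultures. The p-values of single genes therefore measure the spread between these samples, which may be technical. Groups and replicate numbers were taken from the sample titles.

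The authors deposited log2 signal values, 1 per probe set and array, which are gene-level RMA values per the file headers. RMA corrects the background, brings the arrays to 1 common distribution of probe values and summarises the probes of each probe set. The submitters' processing notes name RMA and Partek, without versions. The array design, the annotation release and the scanner settings are not given in the sources used here. An annotated table and the series matrix both held 35557 probe sets for 6 arrays, and their largest difference was 0.0, so the annotated table was used and no column of per-sample values was left out. Because the values had been put on 1 scale before deposit, a shift shared by most genes could not be measured from them. The arrays carry no read depth, and their number limits the precision.

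Probe sets were named from the deposited gene symbols and transcript accessions through a RefSeq gene table of the assembly GRCm38.p6, which was used for names only. That table is of another build than the genome release quoted in the deposited annotation, so no coordinates are given. Of the 35557 probe sets, 25523 had 1 gene name, 6559 were controls, 3473 had no name and 2 had several symbols. The named probe sets included 872 with a symbol found in the deposited table only and 58 named by accession alone. A spreadsheet had turned 26 deposited gene symbols into dates, and 25 of them were restored by accession and 1 by its description. The 25523 named probe sets covered 22093 genes, of which 1864 had more than 1 probe set, and the probe set with the highest mean over the 6 arrays stood for such a gene. No filter on low signal was applied in the main test. Insl3 and Carm1 had no named probe set and are not analysed here.

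The design, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. Differences, siRNA MEF2 minus siRNA control, were tested on the log2 values with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, without covariates, with Benjamini-Hochberg adjustment over the 22093 genes. A gene was called at an adjusted p under 0.05. A fold is 2 to the power of the log2 difference and is given for a gene only where both group means were at least 8, a limit set after the values were seen. Values per group are means ± SD over 3 arrays, and SE is the moderated standard error of limma. On simulated data made for this comparison of 22093 genes, the test recovered 41 of 67 genes changed by 0.3 on the log2 scale (61.2%), 66 of 67 changed by 0.6 (98.5%) and 66 of 66 changed by 1, with 14 false calls. The simulation changed only these genes, with independent noise and no shift between arrays that depended on signal. The real comparison called 20.8% of the genes, so these rates need not hold for it.

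The 26 gene lists covered the MEF2 family, steroid and cholesterol metabolism, glutathione S-transferases, the antioxidant response, regulators of Leydig cells, signalling, known MEF2 targets of muscle and MEF2 coregulators, cell cycle, p53, interferon, the unfolded protein response, energy metabolism, cytoskeleton, matrix and clock genes, and markers of other cell types. The 25 lists with at least 5 measured members were tested with camera of limma, a competitive test that compares a list with all other genes, at a preset correlation between genes of 0.01 and with Benjamini-Hochberg adjustment over the 25 lists. At the preset correlation its p-values rest mainly on the spread across genes, which are not independent replicates. Camera with a correlation estimated for each list and fry, a test of the list on its own, were alternatives. On simulated lists of independent genes the camera test called 100 of 100 shifted lists and 7 of 100 unchanged ones after adjustment; real lists hold correlated genes. The glutathione S-transferase list holds genes that the study followed up after seeing these arrays. Genes were named by this rule: the MEF2 family, the 12 called genes with the largest rise and the 12 with the largest fall without overlap between groups, up to 4 called members of each list with the smallest p, and a fixed set of steroidogenic, alpha-class glutathione S-transferase and Leydig genes. Genes outside the rule are said to have been chosen after their values were seen, and some genes the rule selects are not reported here.

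The alternatives were the replicate number as a block, genes above the median signal only, median centring, quantile normalization, the series matrix values, the mean over the probe sets of a gene, a variance trend with robust estimation, array weights, other thresholds, all probe sets, and leaving out each array in turn. Cyclic loess normalization and a camera test of 830 biological process terms of the deposited annotation, with 10 to 300 genes each, were added after the data were seen. Random lists matched on signal were drawn 10000 times from 100 bins of mean signal, so their counts compare genes and not samples. Gaps between alpha-class probe sets were set beside those of 743 genes with at least 2 probe sets in the upper 4 deciles of signal, with all arrays and without each in turn. Camera was also run on 2 further sets, the histone genes and the NFE2L2 targets, without adjustment and after their values were seen. Tables were read with Python 3.11.15 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.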

Results

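Gene expression was measured in 6 samples of MA-10 mouse Leydig tumour cells, 3 given a small interfering RNA against MEF2A and MEF2D (siRNA MEF2) and 3 given a scrambled one (siRNA control), 48 h before RNA was taken. The comparison asks which genes depend on the MEF2 transcription factors in these cells. Over 22093 genes the median log2 signal per array lay between 7.82 and 7.89. Arrays of the same group correlated at 0.997 to 0.999 and arrays of different groups at 0.995 to 0.996, across genes, which are not independent replicates. The first principal component carried 59.4% of the variance and the second 15.0%. On the second, siRNA MEF2 replicates 1 and 3 lay at opposite ends (11.5 and -11.3), while the control arrays lay between -1.7 and 1.6.

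Both targeted transcripts were lower in every siRNA MEF2 sample than in any control sample. Mef2a (probe set 10564451) had a log2 signal of 10.79 ± 0.01 (SD, n = 3) in siRNA control and 10.01 ± 0.18 (SD, n = 3) in siRNA MEF2. It fell by 0.78 on the log2 scale (SE 0.08), or 1.72-fold, with a limma adjusted p of 8.43e-05. The single values were 10.80, 10.80 and 10.78 in the control samples and 9.80, 10.12 and 10.10 in the siRNA MEF2 samples. Mef2d (probe set 10493177) fell by 0.46 (SE 0.08), or 1.38-fold, from 11.25 ± 0.05 to 10.79 ± 0.17 (SD, n = 3 each; limma adjusted p = 0.00205). A dimmer probe set of Mef2d differed by -0.55. Mef2a and Mef2d were lowest on siRNA MEF2 replicate 1 (9.80 and 10.60), yet Star, Gsta1, Gsta2 and Gsta4 fell least there. On siRNA MEF2 replicates 1 to 3 Star read 8.96, 8.75 and 8.41, and Gsta1 11.15, 10.70 and 10.64. Gsta3 went the other way, with 9.60, 9.68 and 9.84. Array by array, the falls of Star, Gsta1, Gsta2 and Gsta4 thus did not follow the depth of the knockdown. With 3 arrays this was not tested. The family members that were not targeted did not pass the test: Mef2c differed by -0.09 (adjusted p = 0.308) and Mef2b by 0.06 (adjusted p = 0.563), the latter turning to -0.01 after median centring and to -0.00075 without siRNA MEF2 replicate 1. With 4 members the MEF2 family was too small for a list test, and 2 of the 4 passed adjusted over the list alone.

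**Figure D1:**
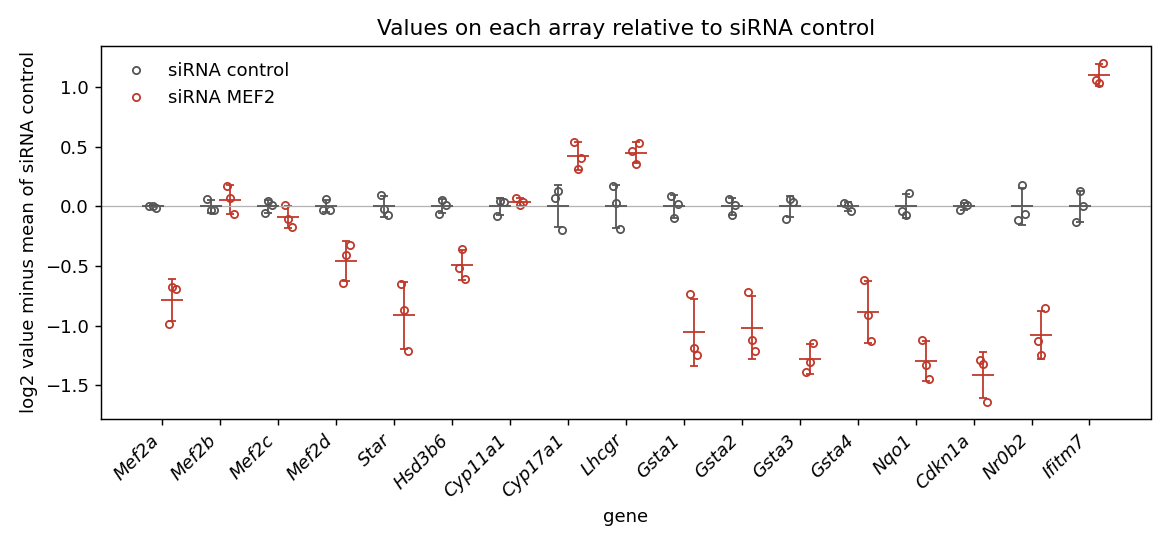
Log2 value of 17 genes on each of the 6 arrays, minus the mean of the 3 siRNA control arrays of that gene (vertical axis, log2 units). Circles are arrays, horizontal marks are group means and bars are SD (n = 3); Mef2a fell by 0.78, Star by 0.91 and Gsta3 by 1.28, while Cyp11a1 differed by 0.04, which turned to -0.03 after median centring.

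The largest falls and rises among called genes without overlap between the groups were as follows. Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, fell 2.66-fold, from 11.59 ± 0.03 to 10.17 ± 0.19 (SD, n = 3 each; log2 -1.41, SE 0.08, limma adjusted p = 4.87e-06). Cd109 fell 2.53-fold and Nqo1, a quinone reductase, 2.46-fold. Slc40a1, the iron exporter ferroportin, fell by 1.32, from 8.94 to 7.62, close to the medians of the negative control probe sets on the siRNA MEF2 arrays (7.16 to 7.53), so no fold is given. Of the 5222 negative controls 1103 lay in the upper 4 deciles of gene signal, so these medians are a reference and not a detection limit. Gsta3 fell 2.43-fold, the mitochondrial carrier Slc25a24 2.22-fold and the tubulin gene Tuba8 2.22-fold. Nr0b2, which encodes the nuclear receptor SHP, fell 2.11-fold, from 9.38 ± 0.16 to 8.30 ± 0.20 (SD, n = 3 each). Gsta1 fell 2.08-fold and the predicted gene Gm10639 2.06-fold. Strip2 fell by 1.08, from 8.88 to 7.80, near those medians, also without a fold. The predicted gene Gm10561 fell by 1.08 to a mean of 6.72, below those medians, likewise without a fold. Among the increases, Ifitm7 rose 2.14-fold, from 9.11 ± 0.13 to 10.21 ± 0.09 (SD, n = 3 each; log2 1.10, SE 0.07, limma adjusted p = 8.53e-06). 1700007K13Rik rose by 0.93, from 7.92 to 8.86. Man2a1, a Golgi mannosidase, rose 1.88-fold, Pttg1ip 1.80-fold, Maged1 1.73-fold and the amino acid transporter gene Slc7a8 1.70-fold. Fgfr4, a fibroblast growth factor receptor, rose 1.65-fold and Prkci, an atypical protein kinase C, 1.62-fold. Sidt2 rose 1.59-fold and Pus7l 1.58-fold. E2f5 rose by 0.69, from 7.42, close to the negative control medians of the control arrays (7.28 to 7.35), to 8.11. The 3 siRNA MEF2 values of each of these genes lay outside the range of the 3 control values, and each kept its direction and its call under every alternative in which it was tested.

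Over all genes, limma called 4586 of 22093 (20.8%), 2002 higher and 2584 lower in siRNA MEF2. Most changes were small: the median fold of a called gene was 1.20, and 17 called genes were at least 1.5-fold higher and 159 at least 1.5-fold lower. Ifitm7 alone was at least 2-fold higher, and 16 genes were at least 2-fold lower. The groups did not overlap for 9011 genes (40.8%), against 10% by chance. Low-signal genes were mostly called higher and high-signal genes mostly lower: the lower 5 deciles of signal held 1251 higher and 160 lower calls, and the upper 4 deciles 462 higher and 2136 lower. The split of 2002 higher and 2584 lower moved with the scaling, to 508 and 3661 after median centring, 931 and 1866 after quantile normalization and 972 and 2125 after cyclic loess, and was 961 and 2779 over genes above the median signal. The total fell to 2522 without siRNA control replicate 2, 2655 without siRNA control replicate 3 and 2483 without siRNA MEF2 replicate 2, and the higher calls fell to 1115, 920, 887 and 814 without siRNA control replicates 1, 2 and 3 and siRNA MEF2 replicate 2. Lower calls numbered 1602 without siRNA control replicate 2 and 1669 without siRNA MEF2 replicate 2.

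**Figure D2:**
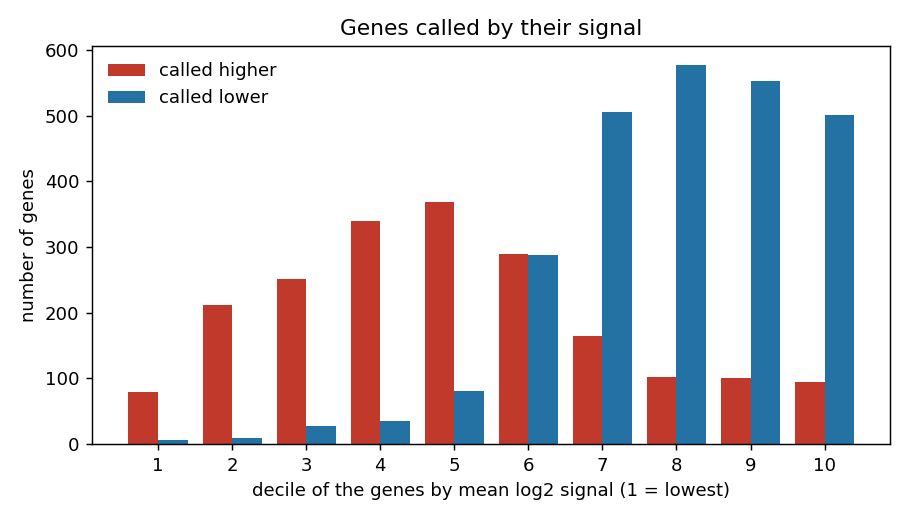
Number of genes called higher and lower in siRNA MEF2 (vertical axis) in each decile of the 22093 genes by mean log2 signal (horizontal axis, 1 is the lowest). Calls in the lower 5 deciles were mostly higher (1251 against 160) and calls in the upper 4 deciles mostly lower (2136 against 462); after cyclic loess the lower 5 deciles held 165 higher and 295 lower calls.

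Steroidogenic genes went both ways, with more of them lower. Of 21 measured members 10 fell, 1 rose and 10 did not pass (10 lower and 3 higher adjusted over the list alone; camera adjusted p = 0.00437, or 0.322 with an estimated correlation; median log2 change -0.14). Star, whose product brings cholesterol into mitochondria and limits the rate of steroid synthesis, fell 1.88-fold, from 9.62 ± 0.09 to 8.71 ± 0.28 (SD, n = 3 each; log2 -0.91, SE 0.11, limma adjusted p = 0.000284). Hsd3b6, a 3-beta-hydroxysteroid dehydrogenase gene, fell 1.41-fold and Cyb5a 1.38-fold. Akr1c18, which encodes a progesterone-degrading enzyme, fell by 0.72, from 6.61 to 5.89, below the negative control medians of all 6 arrays (7.16 to 7.53), so no fold is given. Cyp17a1, which encodes the 17-alpha-hydroxylase and lyase of androgen synthesis, rose 1.34-fold (log2 0.42, SE 0.09, limma adjusted p = 0.00669). Cyp11a1, the first enzyme of the pathway, differed by 0.04 (adjusted p = 0.66), which turned to -0.03 after median centring and to -0.0033 without siRNA control replicate 1. Tspo differed by -0.14 (adjusted p = 0.236) and Hsd17b3, also below the negative control medians, by 0.08 (adjusted p = 0.355). Hsd3b1 fell by 0.46, a call lost with a variance trend and robust estimation (adjusted p = 0.0593), without siRNA control replicate 2 (adjusted p = 0.0886) and without siRNA MEF2 replicate 1 (adjusted p = 0.0643). The electron donor gene Por fell by 0.27, a call lost without siRNA control replicate 1 (adjusted p = 0.0591), control replicate 2 (adjusted p = 0.0504) or siRNA MEF2 replicate 2 (adjusted p = 0.0671). The call of the list was lost over genes above the median signal (adjusted p = 0.0778).

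Among genes of cholesterol uptake and storage, 5 of 18 fell and 2 rose (the same numbers adjusted over the list alone; camera adjusted p = 0.11). Lipa, the lysosomal acid lipase gene, fell 1.52-fold and Scarb1, the receptor for high-density lipoprotein, 1.43-fold (limma adjusted p = 0.00147). Of 22 genes of cholesterol biosynthesis 3 fell and 1 rose (4 lower and 2 higher adjusted over the list alone, camera adjusted p = 0.198), with Insig1, a sterol-sensing regulator, 1.61-fold lower. The counts depended on the scaling: 1 fell and 3 rose after cyclic loess, and 2 fell and 2 rose after quantile normalization.

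Glutathione S-transferases, which conjugate glutathione to reactive compounds, were lower as a family. Of 23 members 12 fell and 2 rose (13 lower and 2 higher adjusted over the list alone; camera adjusted p = 3.49e-06, or 0.322 with an estimated correlation). The study took up genes of this family from these arrays, so the count is not independent evidence of its direction. The alpha class fell furthest. Gsta3 went from 10.98 ± 0.09 to 9.71 ± 0.12 (SD, n = 3 each; log2 -1.28, SE 0.07, limma adjusted p = 4.87e-06). Gsta1 fell 2.08-fold, Gsta2 2.02-fold and Gsta4 1.85-fold (limma adjusted p from 9.73e-05 to 0.000201). Gsta1, Gsta2 and Gm10639 are near-identical paralogs whose probe sets can read each other's transcripts, so their values are uncertain as single genes. Antioxidant genes fell with them: 10 of 24 fell and 0 rose (12 lower and 1 higher adjusted over the list alone; camera adjusted p = 5.14e-07, or 0.322 with an estimated correlation). Txnrd1, the thioredoxin reductase gene, fell 1.71-fold, Srxn1, a sulfiredoxin gene, 1.62-fold and Gss, a glutathione synthetase gene, 1.44-fold (limma adjusted p from 1.75e-05 to 0.000126). Nfe2l2 and Keap1, chosen after their values were seen, encode a transcriptional activator of such genes and its repressor and differed by -0.16 (adjusted p = 0.06) and 0.02 (adjusted p = 0.844).

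Genes of the cell cycle fell as a group. Of 30 measured genes 23 fell and 0 rose (27 lower and 0 higher adjusted over the list alone), with a median log2 change of -0.27 (camera adjusted p = 2.6e-15, or 0.322 with an estimated correlation). The S-phase cyclin genes Ccne1 and Ccne2 fell 1.45-fold and 1.40-fold, the transcription factor gene E2f1 1.46-fold and the mitotic kinase gene Aurkb 1.33-fold (limma adjusted p from 0.000129 to 0.000511). Of 22 genes of p53 signalling and apoptosis 7 fell and 2 rose (8 lower and 2 higher adjusted over the list alone; camera adjusted p = 0.0488, or 0.455 with an estimated correlation). Cdkn1a was among those that fell, while Sesn2, a stress-induced gene, rose 1.36-fold. The call of this list was lost after each of the scaling alternatives (adjusted p from 0.0629 to 0.124), over genes above the median signal (0.163), with the mean over probe sets (0.0536), array weights (0.0519) or fry (0.0653), without siRNA control replicate 1 (0.0609), without siRNA MEF2 replicate 2 (0.0572) and without siRNA MEF2 replicate 3 (0.0874).

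Clock genes were lower: 9 of 19 fell and 1 rose (11 lower and 1 higher adjusted over the list alone; camera adjusted p = 3.33e-06, or 0.322 with an estimated correlation). Npas2 fell 1.74-fold, the repressor genes Bhlhe40 and Bhlhe41 1.68-fold and 1.54-fold, and the nuclear receptor gene Rora 1.41-fold (limma adjusted p from 7.22e-05 to 0.000644). Of 23 genes of the unfolded protein response 11 fell and 1 rose (the same numbers adjusted over the list alone; camera adjusted p = 9.66e-05, or 0.361 with an estimated correlation). Edem1 and Sel1l, which act in degradation of misfolded proteins, fell 1.63-fold and 1.53-fold and Sdf2l1 1.45-fold. Chac1, a glutathione-degrading enzyme gene induced by ATF4, rose 1.48-fold. The call was lost over genes above the median signal (adjusted p = 0.0874).

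Glycolytic genes fell, 9 of 19 with 0 higher (15 lower and 0 higher adjusted over the list alone; camera adjusted p = 6.61e-07, or 0.455 with an estimated correlation). After cyclic loess or quantile normalization 4 of the 19 were called lower and 0 higher. Pfkp, a phosphofructokinase gene, fell 1.40-fold and the hexokinase gene Hk1 1.22-fold. Fry, which tests the list without setting it against other genes, did not call it (adjusted p = 0.109). Of 30 genes of oxidative phosphorylation 2 fell and 0 rose (1 lower adjusted over the list alone; camera adjusted p = 0.484), with a median of 0.00 and a mean of -0.01, the direction of the test. Atp5a1 fell 1.18-fold. Of 29 genes of fatty acid metabolism 3 fell and 1 rose (2 lower adjusted over the list alone; camera adjusted p = 0.0833). Acsl4, which activates arachidonic acid, fell 1.48-fold. This list passed without siRNA control replicate 3 (adjusted p = 0.0362) and without siRNA MEF2 replicate 2 (adjusted p = 0.0389).

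Genes known as MEF2 targets in muscle were higher more often than lower. Of 24 measured genes 6 rose and 1 fell (the same numbers adjusted over the list alone; camera adjusted p = 0.0147, higher, or 0.455 with an estimated correlation). The orphan nuclear receptor gene Nr4a1 rose 1.47-fold, from 9.62 ± 0.07 to 10.18 ± 0.17 (SD, n = 3 each; limma adjusted p = 0.000752), and Jun 1.26-fold. Both are immediate early genes and not specific to muscle. The call of the list was lost over genes above the median signal (adjusted p = 0.0778), after quantile normalization (adjusted p = 0.098) and cyclic loess (adjusted p = 0.0996). After either of these normalizations only 2 members were called higher and 1 lower. Of 21 MEF2 coregulator genes 3 fell and 2 rose (4 lower and 2 higher adjusted over the list alone; camera adjusted p = 0.476), and the median log2 change was 0.01 while the mean and the test were negative (mean -0.02), with Ppp3cb, a calcineurin catalytic subunit gene, 1.31-fold lower. Immediate early genes split, with 4 lower and 3 higher of 23 (the same adjusted over the list alone; camera adjusted p = 0.947). Ier3, Klf10 and Myc fell 1.40-fold, 1.35-fold and 1.26-fold.

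Regulators of Leydig cells split too, with 6 of 25 higher and 4 lower (6 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.974). After cyclic loess or quantile normalization 3 of them were called higher and 1 lower. Lhcgr, the receptor for luteinizing hormone, rose 1.37-fold, from 11.65 ± 0.18 to 12.10 ± 0.09 (SD, n = 3 each; limma adjusted p = 0.00388), and Maf rose 1.24-fold. Nr5a1, the steroidogenic factor 1 gene, rose by 0.20 (adjusted p = 0.0349) and Nr2f2 fell by 0.19 (adjusted p = 0.0344). The call of Nr5a1 was lost after median centring (adjusted p = 0.172) and without any 1 array except siRNA MEF2 replicate 2 (adjusted p from 0.0646 to 0.0953). That of Nr2f2 was lost after quantile normalization (adjusted p = 0.0865), after cyclic loess (adjusted p = 0.056) and without any 1 array except siRNA MEF2 replicate 3 (adjusted p from 0.0562 to 0.116). Gata4 differed by -0.18 (adjusted p = 0.0625) and passed in 5 of 15 alternatives, among them median centring (adjusted p = 0.0211) and the fit without siRNA control replicate 1 (adjusted p = 0.0407). Of 22 genes of cAMP signalling, the pathway through which luteinizing hormone acts, 6 fell and 0 rose (the same adjusted over the list alone; camera adjusted p = 0.0833); Akap12, a kinase anchor gene, was 1.44-fold lower and Mapk3 1.25-fold lower.

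Cytoskeletal genes fell in 7 cases and rose in 2 of 24 (the same adjusted over the list alone; camera adjusted p = 0.0417, or 0.478 with an estimated correlation). Tagln2 fell 1.43-fold, the tropomyosin genes Tpm4 and Tpm2 1.37-fold and 1.30-fold, and the lamin gene Lmna 1.38-fold. The call of the list was lost after each of the scaling alternatives (adjusted p from 0.0586 to 0.0883), over genes above the median signal (0.164), with the mean over probe sets (0.0562), array weights (0.0786) or fry (0.0653), without siRNA control replicate 1 (adjusted p = 0.0609) and without siRNA MEF2 replicate 3 (adjusted p = 0.0976). Of 26 matrix genes 3 fell and 2 rose (3 lower and 7 higher adjusted over the list alone; camera adjusted p = 0.106). The median of this list was 0.10, and it passed over genes above the median signal (adjusted p = 0.0357) and with fry (adjusted p = 0.0388).

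Lists of markers of other cell types did not pass the camera test. Germ cell markers rose in 6 of 20 cases with 0 lower (the same adjusted over the list alone; camera adjusted p = 0.0745, fry adjusted p = 0.000241), with Ddx4 higher by 0.39. After cyclic loess 1 of them, Ddx4, was called. Macrophage and leukocyte markers rose in 4 and fell in 1 of 18 (6 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.0869), and Cd68 fell 1.45-fold. After cyclic loess or quantile normalization 2 of these markers were called higher and 2 lower. Sertoli cell markers rose in 4 and fell in 1 of 19 (the same adjusted over the list alone; camera adjusted p = 0.476); Rhox5 was 1.25-fold higher and Gata1 1.38-fold lower. Endothelial and peritubular markers rose in 1 and fell in 1 of 16 (1 lower adjusted over the list alone; camera adjusted p = 0.683), with Cdh5 1.34-fold lower. Adrenal and ovary markers fell in 4 of 15 with 0 higher (4 lower and 2 higher adjusted over the list alone; camera adjusted p = 0.198), among them Lhx2 (1.30-fold) and Amhr2 (1.29-fold). Interferon genes, which can respond to small interfering RNA, fell in 3 of 25 with 0 higher (the same adjusted over the list alone; camera adjusted p = 0.683), with a median of 0.05, a mean of -0.00 and a negative test direction. Ifitm7, annotated as an interferon induced transmembrane protein and not a member of this list, rose 2.14-fold. Within the list, Eif2ak2 and Stat2 fell by 0.22 and 0.21. The calls of Eif2ak2 and Stat2 were lost without siRNA control replicate 2 (adjusted p = 0.0861 and 0.0925) and without siRNA MEF2 replicate 2 (0.0582 and 0.0629). That of Eif2ak2 was also lost after quantile normalization (0.111), after cyclic loess (0.0634) and without siRNA MEF2 replicate 3 (0.0545), and that of Stat2 without siRNA control replicate 3 (0.0573).

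**Figure D3:**
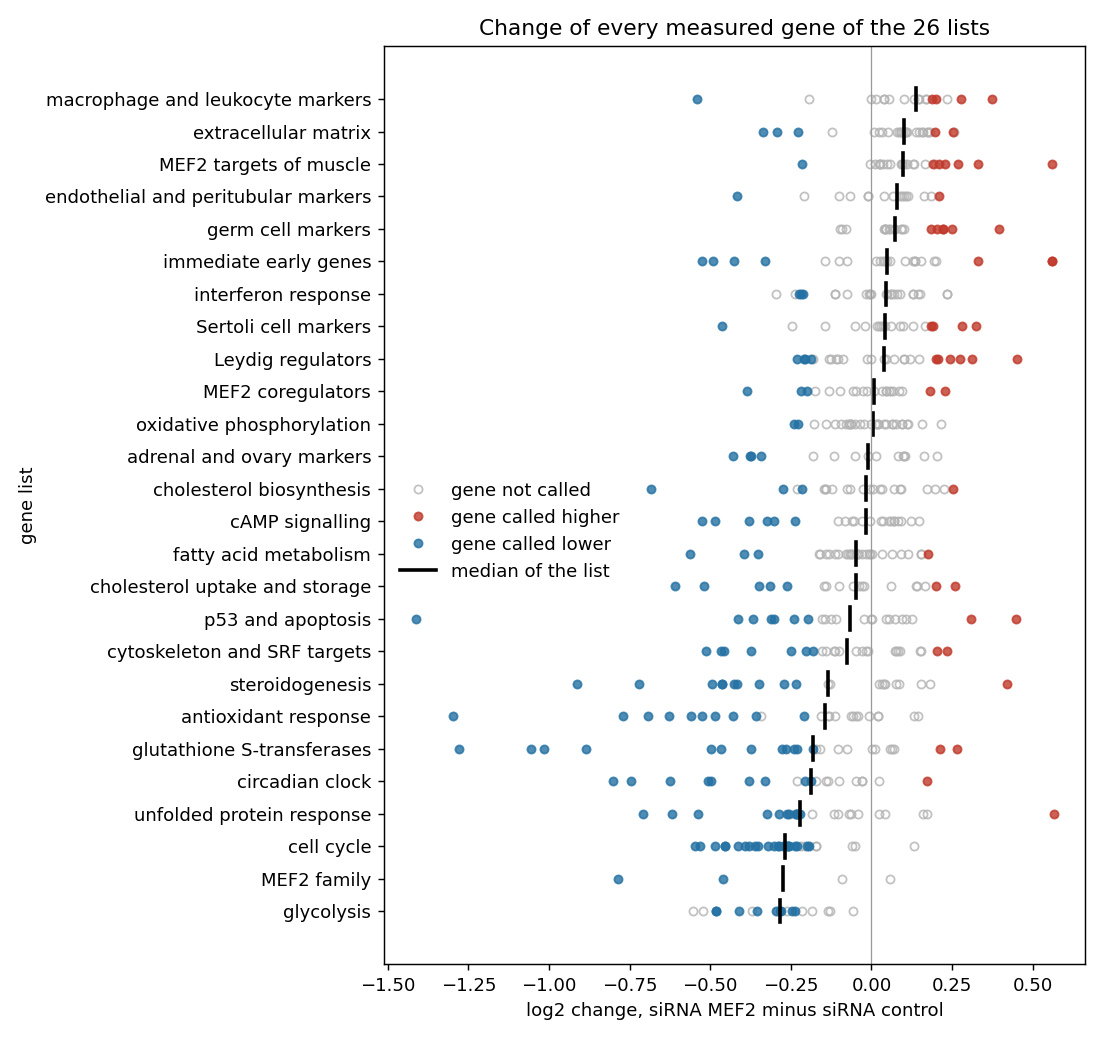
Log2 change of each measured gene of the 26 lists (horizontal axis, siRNA MEF2 minus siRNA control), with genes called higher in red, called lower in blue and not called as open circles, and the median of each list as a black bar. Medians ran from -0.28 (glycolysis) to 0.14 (macrophage and leukocyte markers); several medians within 0.08 of 0 change sign under other scalings.

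Camera called 10 of 25 lists at the preset correlation and 0 with an estimated correlation, where the smallest adjusted p was 0.322 and 3 lists had an unadjusted p under 0.05. Fry called 9 lists. The preset test also called up to 12 lists when the 6 arrays were divided in ways that mixed the groups.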

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

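All tests of explanations in this part except the counts over other splits of the arrays were chosen after the results were seen. The test of the trend with signal was first made on spike-in probe sets, where the groups overlapped and nothing was decided, and the 2 tests given here then took its place. Shared reading of alpha-class transcripts was first tested on the group means, where the difference of Gsta3 and Gsta1 (-0.22, 95% interval -0.55 to 0.10) decided nothing. The gaps over the arrays were tested next, and that the outcome must hold without any 1 array was required only after the gap of Gsta3 was seen to rest on siRNA MEF2 replicate 1; before that, shared reading was counted as argued against for Gsta3. A wider set of NFE2L2 targets that shared genes with the antioxidant list was also lower and was narrowed to 14 genes after its values were seen.

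Probe sets outside the comparison of genes also differed between the groups. Of 5222 probe sets that the deposited annotation lists as negative controls, 112 were called higher and 34 lower in siRNA MEF2. Of 3475 probe sets without a single gene name, 78 were called higher and 30 lower, with 0 at least 1.5-fold higher and 2 at least 1.5-fold lower. Of 1324 positive control probe sets 12 were called higher and 67 lower.

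The first pattern was that genes of low signal were mostly called higher (1251 against 160 in the lower 5 deciles) and genes of high signal mostly lower (2136 against 462 in the upper 4 deciles). A scaling difference between the arrays that depends on signal was tested for each end. For the falls at high signal it stayed open. After cyclic loess 1500 genes there were still called lower against 669 higher, and after quantile normalization 1336 against 634. Both normalizations were fitted on all probe sets, among them negative controls with median changes of 0.14 to 0.22 in these deciles. Cyclic loess moved the median changes of the genes there from between -0.08 and -0.06 to between -0.04 and -0.02. A trend among genes was thus not fully taken out, and the calls that remained cannot decide. The rule written for this test counted mostly lower calls after both normalizations as against a scaling difference. That outcome was met and was set aside for this reason. For the rises at low signal the scaling difference stayed open too. Negative controls of the same signal had a median change of 0.0131, with array medians of -0.14, 0.04 and 0.14 in siRNA MEF2 and -0.03, 0.03 and 0.01 in siRNA control. After cyclic loess calls at low signal were 165 higher and 295 lower. Spike-in probe sets went lower (9 of 9 means, from -0.27 to -0.05), by array medians on siRNA MEF2 replicates 1 and 2. These medians were -0.26, -0.16 and -0.03, against 0.02, 0.01 and -0.03 in siRNA control. Negative controls of high signal went higher (median 0.18) on siRNA MEF2 replicates 2 and 3 only (array medians -0.03, 0.22 and 0.33, against -0.02, -0.01 and 0.03 in siRNA control). No biological explanation was tested.

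The second pattern was the fall of cell cycle genes. A trend with signal as the whole source was argued against by random lists matched on signal. The list's median change was -0.27, against -0.06 for the median of the matched lists. After cyclic loess these values were -0.22 and -0.02, and 0 of 10000 matched lists lay as low, a count over genes and not samples. The camera adjusted p of the list after cyclic loess was 1.53e-12, or 0.25 with an estimated correlation. These p-values cannot decide, because cyclic loess left part of the trend and the preset test rests on the spread across genes. A halt of the cycle through more Cdkn1a mRNA was argued against by the change of Cdkn1a itself, -1.41. A smaller share of cells in S phase may account for the fall of the list, as a hypothesis. Outside the list, 41 replication-dependent histone genes had a median change of -0.17, with 0 higher and 21 lower. Of 10000 matched lists 0 lay as low, a count that treats the 41 genes as independent. Their estimated correlation was 0.31, and camera with it gave an unadjusted p of 0.065. Genes of mitosis fell too (77 of 188, with 4 higher), so these values do not single out S phase. Cell numbers and cycle phases were not measured here, and whether the small interfering RNA acted through MEF2 or off target cannot be tested in this design.

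The third pattern was the fall of alpha-class glutathione S-transferase genes. A trend with signal was argued against by its size. The deciles of signal had median changes between -0.08 and 0.11, while Gsta1 to Gsta4 fell by 0.88 to 1.28. Cyclic loess could hardly take out falls of this size, and the largest limma adjusted p of the 4 genes after it was 0.000615. A probe set that read the Gsta1 transcript alone would keep its gap to Gsta1 constant over the 6 arrays. One that read it beside its own transcript need not, so a varying gap cannot argue against shared reading in part. For Gsta3 the gap varied by 0.81, more than in 741 of 743 pairs of probe sets of the same gene. Without siRNA MEF2 replicate 1 it varied by 0.35, more than in 672 of the pairs without that array, so shared reading stayed open. For Gsta4 the gap varied by 0.34, which leaves shared reading open too. For Gsta2 it varied by 0.0886, under the median of 0.139 for such pairs. Shared reading may apply there, although genes regulated together could keep their gap as well. Lower activity of NFE2L2, an activator of antioxidant genes, may contribute, as a hypothesis: 14 of its textbook targets outside the lists had a median change of -0.33, with 0 higher and 12 lower, and 0 of 10000 matched lists lay as low, a count that treats genes regulated together as independent (camera with an estimated correlation gave an unadjusted p of 0.00651).

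The 10 ways of dividing the 6 arrays into 3 and 3 are too few for a share under 0.05. The real division called 4586 genes, and the highest of the others 0 with limma (8126 against at most 789 genes at an unadjusted p under 0.05), so 1 of 10 reached the real count. The other divisions mix the groups, so any difference between the groups adds to their spread and lowers their count of genes. Their count is therefore no measure of chance. The real division called 10 lists against a highest of 12 in the others, so 2 of 10 reached that count, the other being siRNA control replicates 1 and 2 with siRNA MEF2 replicate 1 against the rest. It called 54 annotation terms against a highest of 53, so 1 of 10 reached it.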

How the results depend on the processing

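Cyclic loess was chosen after the data were seen and the other alternatives before. Of 119 named genes called, 118 kept their call with the replicate number as a block, 105 after median centring, 99 after quantile normalization, 101 after cyclic loess and 93 to 107 without 1 array, and 0 turned. Mef2a and Mef2d kept their direction and call in all 15 alternatives. Mef2b turned to -0.0083 after median centring and lay between -0.00075 and 0.12 without 1 array, and Cyp11a1 turned to -0.0275 and lay between -0.0033 and 0.0593. The total of 4586 calls became 2797 after quantile normalization, 2226 over all probe sets and 176 at 1.5-fold or more, with adjusted or unadjusted p. Calls higher, 2002 as reported, numbered 961 over genes above the median signal, 508 after median centring, 931 after quantile normalization, 972 after cyclic loess, 691 over all probe sets and 17 at either threshold of 1.5-fold. Calls lower, 2584 as reported, numbered 1535 over all probe sets and 159 at either threshold. The fit over all probe sets tested and counted probe sets, among them controls and unnamed ones, and not genes. It was not one of the 15 alternatives for Mef2a and Mef2d, and in it Mef2d had a limma adjusted p of 0.0352. Without 1 array the total lay between 2483 and 4286, the higher calls between 814 and 2075 and the lower calls between 1602 and 2616. Lists called, 10 as reported, numbered 6 over genes above the median signal and 0 with an estimated correlation. Lists that were not called turned direction as follows, by adjusted p. Cholesterol biosynthesis turned over genes above the median signal (0.854), after quantile normalization (0.974) and after cyclic loess (0.762). MEF2 coregulators turned in these alternatives (0.995, 0.9004 and 0.81), as did oxidative phosphorylation (0.439, 0.48 and 0.266), which also turned without siRNA MEF2 replicate 2 (0.867; 0.193 to 0.867 without 1 array). Endothelial and peritubular markers turned after quantile normalization (0.602) and cyclic loess (0.571). Leydig regulators turned with array weights (0.921) and without siRNA control replicate 1 (0.89) or siRNA MEF2 replicate 3 (0.974), in a range of 0.766 to 0.974 without 1 array. Immediate early genes turned without siRNA control replicate 3 (0.94) or siRNA MEF2 replicate 1 (0.485), in a range of 0.358 to 0.942, and interferon genes without siRNA MEF2 replicate 3 (0.932), in a range of 0.223 to 0.932. Stricter thresholds lower counts by construction, and for the other changes the cause was not tested. Fewer genes or samples did not always lower counts. Lower calls numbered 2779 over genes above the median signal and 2616 without siRNA MEF2 replicate 1. Higher calls numbered 2075 without siRNA MEF2 replicate 3. Samples with the same replicate number shared only a number: their deviations from the group means correlated at 0.113, 0.0763 and 0.0961, and 6 of 6 correlated best with their own number, a hint from the data alone. With the block 5319 genes and 10 lists were called. Signal near that of the negative controls limits low-signal genes.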

Other observations

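The annotation terms and the genes named in this part were tested or chosen after the results were seen. Of 830 biological process terms camera called 54, 48 lower and 6 higher, of which 14 were called after cyclic loess too, all 14 lower. With an estimated correlation 0 were called (smallest adjusted p = 0.892, 11 terms at an unadjusted p under 0.05), and a division of the arrays that mixed the groups called 53.

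Terms of chromosome duplication and division led the lower ones. In mitosis 77 of 188 genes fell and 4 rose, in DNA replication 46 of 106 fell and 3 rose, and in nucleosome assembly 33 of 74 fell and 0 rose. Anln, which encodes a protein of the contractile ring, fell by 0.61 (SE 0.06, limma adjusted p = 5.18e-05), Lin9, part of a complex that regulates cell cycle genes, by 0.67 and the histone gene H2ac4 by 0.77. Rb1, which encodes the retinoblastoma protein, a brake on entry into S phase, also fell, by 0.76 (SE 0.07, limma adjusted p = 3.48e-05).

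In lysosome organization 6 of 15 genes fell and 0 rose, where Chmp5 fell by 0.66 and Cln6 fell by 0.53, beside the fall of Lipa. In one-carbon metabolism 9 of 28 fell and 0 rose.

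Among the NFE2L2 targets outside the lists, Cbr3, a carbonyl reductase gene, fell by 0.83, the ferritin light chain gene Ftl1 by 0.52 and Ugdh by 0.50. Tkt and Ephx1 differed by -0.07 (adjusted p = 0.374) and -0.05 (adjusted p = 0.625).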
